A study of Homo sapiens with 30 samples.

How the data were processed

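RNA-seq and CUT&RUN were measured in MCF-7 cells. Per the labels' protocols, cells for RNA-seq grew for 3 days in phenol red-free medium with 10% serum, RNA was selected by its poly(A) tail, and libraries were made with a directional kit. The samples are titled as biological replicates. Cells for CUT&RUN grew for 3 days in medium with 10% charcoal-stripped serum, which is low in oestrogens, before 1 hour of treatment. Per the submitters' processing notes, HISAT2 2.2.1 and featureCounts of Subread 2.0.1 were used with hg38 for RNA-seq, and Bowtie2, SAMtools and MACS2 with the same build for CUT&RUN; versions of the last 3, the MACS2 control and the strand setting of the counting are not given in the sources used here.

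The authors deposited raw counts per gene, not normalised. The table has 27647 rows, of which 3219 repeat a gene's counts under another Ensembl identifier; 24428 genes remained, 24422 of them matched by Entrez identifier to the RefSeq gene table of GRCh38. In the peak lists, the −log10 p and −log10 q values and the fold of each peak are those deposited by the authors from MACS2, per the labels, and were used only to rank or filter peaks within a list. Peaks were listed per file. In the stable lines each sample of replicate 2 has 3 files; these are numbered 2, 3 and 4 while the sample is titled as replicate 2, and whether they come from separate cultures is not given in the sources used here. They count as 1 sample, its number of peaks is the mean of its files, and its regions are those in at least 2 files.

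Genes were filtered with filterByExpr (minimum count 10, total 15), scaled with TMM and tested with edgeR 4.0.16 (robust quasi-likelihood F test, R 4.3.3, no block) with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors of log2 fold changes were derived from the F statistic. The common dispersion was 0.0125. Gene lists, 34 in number, were fixed before the data were examined and tested with camera (limma 3.58.1, preset correlation 0.01, prior count 2), camera with an estimated correlation, and fry, which tests whether a list's genes move one way; 32 lists had enough members. Totals of 1865138 to 42945661 counts set the precision, and the median count of a tested gene was 54 to 56 in the NUTF2 libraries and 1073 to 1283 in the empty-vector libraries. Chi-square per gene between replicates was 2.15 to 43.5, above sampling noise alone, so the libraries are not copies of each other. With 3 against 3 an exact permutation test cannot go below p = 0.1, so the adjusted p of edgeR rests on its model of the spread across genes.

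Named genes were set before the data were examined: NUTF2 and ESR1; the 10 highest and 10 lowest log2 fold changes among called genes with a symbol, a mean of at least 1 CPM and groups that do not overlap; up to 4 called members of each described list (or 2 if none was called); 9 loci for peaks within 50 kb; the 5 strongest peaks of the gained and HA sets, of which the first ones are given; and 5 called genes each way with an E2 region within 10 kb. The described lists, 10 in number with 3 of other cell types, and the genes named only for being called with each chromosome scaled by itself were chosen after their values were seen.

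Peaks overlapping by at least 1 bp counted as shared. Chance was taken from 100 placements at random on the same chromosome and from 100 local shifts of 10 to 500 kb. Local shifts had no limit at a sequence's upper end, so peaks on short unplaced sequences could be moved off them. Shares have exact (Clopper-Pearson) 95% intervals, which cover counting error only. The gene table gives no strand here, so distance was measured from the gene's annotated interval in place of the transcription start planned. The planned search for oestrogen response elements was not run, as no genome sequence was used here. Genes with a peak were tested with Fisher's exact test against tested genes that were not called (SciPy 1.17.1). Genes are not independent replicates.

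Alternatives planned were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, other filters and thresholds, a replicate block, leaving out each sample, stricter peaks, 50% reciprocal overlap, main chromosomes only, lists of equal length, other rules for several files and other distances. Chosen after seeing the data were scaling each chromosome by itself (TMM factors per chromosome and library as edgeR offsets), thinning the empty-vector libraries to the depth of the NUTF2 libraries, leaving out pseudogenes, matching genes by chromosome or length, and the test of oestradiol-induced genes at E2 regions.

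The gene tests were tested on simulated counts with the real means, library sizes and trended dispersions and 200 genes changed by 1.5-fold or 2-fold. Over 13346 genes without chromosome shifts, edgeR found 50% of the 1.5-fold and 70% of the 2-fold changes, with 4 unchanged genes among 124 calls. With the measured chromosome shifts added, over 13299 genes, 2650 genes were called of which 2517 had no change of their own; with each chromosome scaled by itself 120 were called, 3 of them unchanged, and 44% and 73% of the changes were found. Overlap counts were checked on planted intervals.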

Results

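MCF-7 is a human breast cancer line of luminal type that depends on oestrogen receptor alpha (ERα). NUTF2, nuclear transport factor 2, carries the small GTPase Ran into the nucleus. The series holds 30 samples. RNA-seq compared 3 libraries of a stable MCF-7 line with an empty vector and 3 of a line overexpressing HA-tagged NUTF2. CUT&RUN, which maps where an antibody's target sits on chromatin, was done on 24 samples, and 16 of them had peak lists, 28 lists in all. These cover ERα in parental MCF-7 with vehicle or 10 nM oestradiol (E2), ERα in both stable lines with vehicle or 1 µM 4-hydroxytamoxifen (4OHT, the active form of tamoxifen), and the HA tag in the NUTF2 line with the same treatments. Treatments lasted 1 hour, and each group had 2 samples. The other 8 samples, IgG controls and HA in the empty-vector line, were not analysed here. Total gene counts were 35278609 to 42945661 in the empty-vector libraries and 1865138 to 1958634 in the NUTF2 libraries, a ratio of means of 20.5, so values in the NUTF2 group carry the larger counting error.

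NUTF2 was higher in the line made to overexpress it. Its level was 304 ± 22 normalised CPM in the NUTF2 libraries and 101 ± 10.2 in the empty-vector libraries (SD, n = 3 each), a 3.02-fold difference (95% interval 2.65 to 3.43; log2 fold change 1.59, SE 0.094, edgeR adjusted p = 1.08e-05). The gene (Entrez 10204) lies on chromosome 16 from 67846933 to 67872567 in GRCh38. ESR1, which encodes ERα, was at 257 ± 19.0 CPM against 289.8 ± 10.4 and was not called (log2 fold change -0.17, adjusted p = 0.158).

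**Figure D1:**
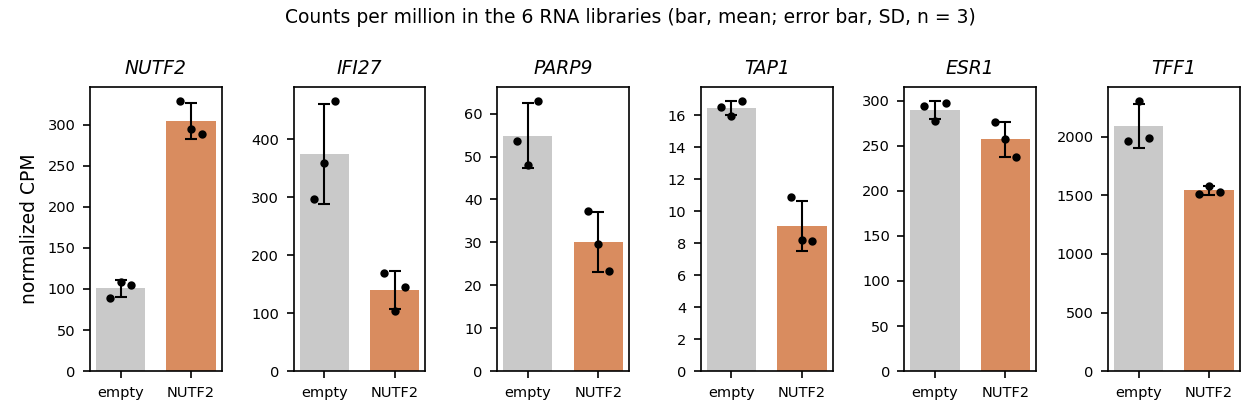
Normalised CPM of 6 genes in the 6 RNA libraries. Bars are means, error bars are SD (n = 3), points are libraries, and every axis starts at 0. NUTF2 libraries are higher for NUTF2 and lower for IFI27, PARP9 and TAP1; the log2 fold change of TFF1 is -0.44, and 0.11 once each chromosome is scaled by itself.

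Over all genes, 2229 of 13452 tested differed between the lines in edgeR's quasi-likelihood test, of which 1452 rose and 777 fell. Upper-quartile scaling gave 1247 that rose and 1001 that fell, and the fit without a low-count filter 1258 and 1119. Most differences were small: 73 genes had an absolute log2 fold change of at least 1. The CPM of the groups did not overlap for 35.7% of genes, where chance gives 10%. The count was 1148 without empty-vector replicate 3 and 1291 without NUTF2 replicate 2.

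The direction of a gene's difference followed the chromosome it lies on. Among genes of at least 10 CPM, the median log2 fold change was 0.58 on chromosome 1, 0.34 on chromosome 17, 0.32 on chromosome 12 and 0.24 on chromosome 2. It was -0.45 on chromosome 22, -0.54 on chromosome 21, -0.60 on chromosome 13 and -0.64 on chromosome 18. On chromosome 1, 799 of 1381 tested genes rose and 0 fell; on chromosome 18, 107 of 176 fell and 0 rose. Mitochondrially encoded genes had a median of -1.04, and of -0.65 without NUTF2 replicate 1. When each chromosome was scaled by itself, an alternative chosen after seeing the data, edgeR called 8 genes, all of which rose. Of the 13452 genes tested there, 706 had an unadjusted p under 0.05, near the share of 0.05 that chance gives. The 8 were NUTF2, RPL13AP5, KRT18P55, EIF3CL, POTEJ, KANTR, PGAM4 and RPL13AP20. NUTF2 kept a log2 fold change of 1.58 (SE 0.10, adjusted p = 2.52e-05). Leaving out a library gave 1 (without NUTF2 replicate 3), 2 (without NUTF2 replicate 1, or 2), 4 (without empty-vector replicate 3), 5 (without empty-vector replicate 2) or 15 genes (without empty-vector replicate 1), of which 8 rose and 7 fell in the last case and the rest all rose. Together with a replicate block this scaling gave 24 genes that rose and 22 that fell.

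**Figure D2:**
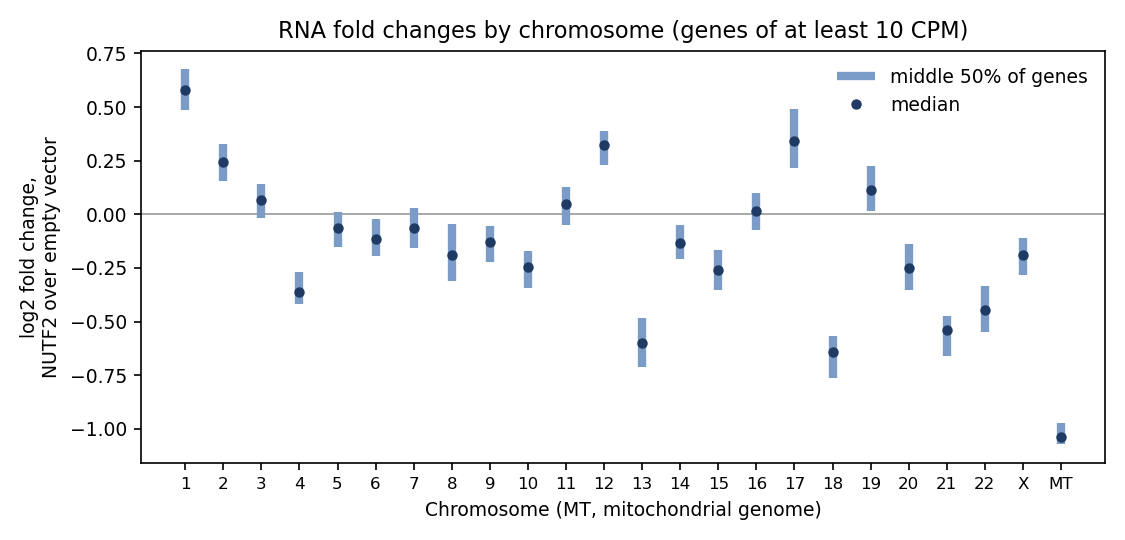
Log2 fold change of NUTF2 over empty-vector libraries for genes of at least 10 CPM, by chromosome. Points are medians and bars span the middle 50% of genes. Chromosome 1 has the highest median at 0.58, chromosome 18 the lowest of the nuclear chromosomes at -0.64, and the mitochondrial genome lies at -1.04.

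**Figure D3:**
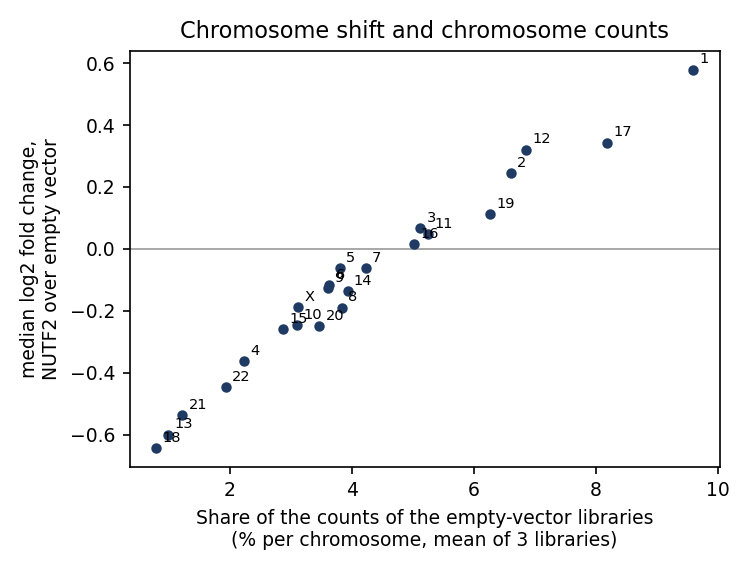
Median log2 fold change of each nuclear chromosome against its share of the counts of the empty-vector libraries (percent, mean of 3 libraries). Each point is 1 of 23 chromosomes. Chromosome 18, with 0.796% of counts, lies at -0.64 and chromosome 1, with 9.59%, at 0.58.

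Some interferon-stimulated genes were lower in the NUTF2 line. Of 38 measured members, 8 fell, 0 rose and 30 were not called, ISG15 (0.12) and STAT2 (0.20) among the latter (9 fell adjusted over the list alone). The median log2 fold change was -0.62 and the list was called by camera (adjusted p = 3.81e-05). With an estimated correlation the call was lost (p = 0.14, adjusted p = 0.936). Fry did not call this list (adjusted p = 0.194) or any other. IFI27 fell from 374 ± 85.7 to 139.6 ± 33.1 CPM (log2 fold change -1.42, SE 0.23, adjusted p = 0.00791), PARP9 from 54.9 ± 7.58 to 30.1 ± 7.03 CPM, TAP1, a subunit of the peptide transporter for antigen presentation, from 16.4 ± 0.466 to 9.07 ± 1.57 CPM, and MX1, an antiviral GTPase, from 3.57 ± 0.695 to 0.881 ± 0.584 CPM (SD, n = 3). Relative to their chromosomes the list's median was -0.56 and camera's adjusted p = 1.49e-14, but adjusted p = 0.977 with an estimated correlation. In that fit PARP9 had a log2 fold change of -0.94 (adjusted p = 0.0755) and IFI27 of -1.30 (adjusted p = 0.443). There edgeR called 0 of the 38 members over all genes, and 6 fell adjusted over the list alone. Fry gave the list an adjusted p of 0.401 in that fit. MX1 lies on chromosome 21, whose genes were lower as a whole, and was not called without NUTF2 replicate 2 (-1.76, adjusted p = 0.11) or 3 (-1.75, adjusted p = 0.106).

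Genes that oestradiol induces in MCF-7 cells showed no common direction. Of 54 measured, 7 rose, 7 fell and 40 were not called (8 rose and 9 fell adjusted over the list alone), with a median log2 fold change of 0.002 and an adjusted p of 0.952 in camera. CELSR2 (0.87) and PDZK1 (0.88), on chromosome 1, and RARA (0.59), a retinoic acid receptor gene on chromosome 17, rose. XBP1 on chromosome 22 fell by 0.47 on the log2 scale. With each chromosome scaled by itself, 0 members were called in edgeR, CELSR2 was at 0.30, PDZK1 at 0.31, RARA at 0.26 and XBP1 at -0.01. PGR, MYC and CCND1 were not called in either fit, and neither was GREB1 (0.28, adjusted p = 0.0688), which was called without empty-vector replicate 1 (0.34, adjusted p = 0.0193) or NUTF2 replicate 3 (0.36, adjusted p = 0.0336).

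Among genes of oestrogen receptors and of their cofactors, 1 rose and 7 fell of 21. PRMT2, on chromosome 21, fell by 0.79 on the log2 scale and TLE3, on chromosome 15, by 0.39, while NCOR2, a corepressor gene on chromosome 12, rose by 0.42. Relative to their chromosomes these were -0.24, -0.11 and 0.12, and edgeR called 0 of the 21. NCOR2 was not called without empty-vector replicate 3 (0.35, adjusted p = 0.0681) or NUTF2 replicate 1 (0.36, adjusted p = 0.0513). Of 34 genes of the Ran cycle, importins and exportins, 9 rose, NUTF2 included, and 7 fell. RCC1, the exchange factor for Ran, IPO9 and KPNA6, all on chromosome 1, rose by 0.69, 0.68 and 0.71, and were at 0.13, 0.11 and 0.14 relative to their chromosome; NUTF2 was the 1 member called there. Of 30 nucleoporins, 7 rose and 3 fell. SEH1L on chromosome 18 fell by 0.73 on the log2 scale, and NUP85 on chromosome 17 rose by 0.51; relative to their chromosomes they were at -0.09 and 0.17. Camera called none of these lists (adjusted p = 0.514 for receptors with cofactors and for nucleoporins, 0.344 for transport genes).

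Of 15 luminal markers, 4 rose and 1 fell. KRT18 (0.48) and KRT8 (0.42), keratins of simple epithelium, lie beside each other on chromosome 12 and were at 0.18 and 0.12 relative to it. KRT8 was not called without empty-vector replicate 3 (0.36, adjusted p = 0.061) or NUTF2 replicate 1 (0.27, adjusted p = 0.0586). TFF1, a secreted trefoil peptide gene on chromosome 21, was lower at 1541 ± 35.5 against 2089 ± 190.1 CPM (log2 fold change -0.44, adjusted p = 0.00273), and relative to its chromosome the sign turned (0.11, adjusted p = 0.92). Of 16 mesenchymal genes 4 rose, among them TGFB2 (1.05, chromosome 1) and FN1, fibronectin (0.48, chromosome 2). FN1 lost its call without empty-vector replicate 2 or 3 (adjusted p = 0.0678 and 0.0997) or NUTF2 replicate 1 or 2 (adjusted p = 0.0947 and 0.0766). Relative to the chromosome TGFB2 was at 0.48 and camera called this list (adjusted p = 0.0317), though not with an estimated correlation (adjusted p = 0.977) and not without chromosome scaling (adjusted p = 0.344). Of 45 large-subunit ribosomal protein genes, 13 rose and 4 fell; RPL5 (0.74), RPL11 (0.69) and RPL22 (0.65), all on chromosome 1, were at 0.18, 0.12 and 0.09 relative to it. That list was at adjusted p = 0.0502 in camera and, relative to chromosomes, at adjusted p = 0.000171, with adjusted p = 0.977 for an estimated correlation. Of 34 G2 and mitosis genes, 5 rose and 4 fell, BIRC5 (0.69) and NUF2 (0.82) among those that rose; relative to their chromosomes these were at 0.36 and 0.25 and 0 were called. The luminal and mitotic lists were not called by camera (adjusted p = 0.588 and 0.952). Of fibroblast, leukocyte and endothelial markers, 4, 2 and 2 genes were measured and 0 were called.

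The 13 mitochondrially encoded protein genes had a median log2 fold change of -1.04 with 0 called in edgeR, and camera called the list (adjusted p = 0.00584; adjusted p = 0.936 with an estimated correlation). These genes made up 0.593% of counts in NUTF2 replicate 1, 3.1% and 2.45% in the other NUTF2 libraries, and 3.61% to 4.71% in the empty-vector libraries. Without NUTF2 replicate 1 the median was -0.65 and 12 of the 13 were called, among them MT-CO2 (-0.73, adjusted p = 0.0109; -1.12 and adjusted p = 0.348 with it) and MT-ND3 (-0.72, adjusted p = 0.00336).

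The genes with the highest fold changes were mostly members of near-identical families, whose reads counting can divide between copies, so these values are uncertain. POTEJ and POTEI of the POTE ankyrin family had log2 fold changes of 4.36 and 3.28, BOLA2B 4.29, NPIPB13 3.28, PGAM4, a retrocopy of PGAM1, 3.78, and the pseudogenes RPL29P2, RPL13AP20 and KRT18P55 3.88, 2.95 and 2.59. KANTR (2.74) and ZBTB18 (2.52), a zinc finger repressor gene, complete the 10. In NUTF2 replicates 1 to 3, BOLA2B had 4, 2 and 25 counts and RPL29P2 6, 4 and 3, while KRT18P55 had 28, 20 and 21. KRT18P55 rose from 2.03 ± 0.210 to 12.3 ± 1.95 CPM (SD, n = 3). Without NUTF2 replicate 3, BOLA2B (2.48, adjusted p = 0.0853) and ZBTB18 (2.17, adjusted p = 0.059) were not called, nor was NPIPB13 without NUTF2 replicate 2 (2.48, adjusted p = 0.0853). The 10 genes that fell most were FGFBP3 (-2.41), NCAM2 (-2.00), MX1 (-1.99), MTRF1 (-1.72), DDX60 (-1.70), PARP10 (-1.70), ZMAT1 (-1.47), LRP5L (-1.45), LOC344967 (-1.43) and IFI27 (-1.42). Most of these folds rest on few counts. In NUTF2 replicates 1 to 3, FGFBP3 had 0, 1 and 3 counts, NCAM2 2, 2 and 4, and MX1 3, 1 and 1. IFI27 had 327, 190 and 268. Without NUTF2 replicate 2, FGFBP3, NCAM2, MX1, MTRF1, DDX60, PARP10, ZMAT1 and LOC344967 were not called (adjusted p = 0.076, 0.0513, 0.11, 0.0698, 0.104, 0.161, 0.0544 and 0.0605). Without replicate 1, FGFBP3, DDX60, PARP10, ZMAT1 and LOC344967 were not (adjusted p = 0.0501, 0.0681, 0.112, 0.0641 and 0.147). Without replicate 3, MX1, DDX60, ZMAT1 and LOC344967 were not (adjusted p = 0.106, 0.0607, 0.0748 and 0.103), and PARP10 was not without empty-vector replicate 2 (adjusted p = 0.0551). None of these 10 was called with each chromosome scaled by itself. In that fit 706 of 13452 genes had an unadjusted p under 0.05 in edgeR, near the share of 0.05 that chance gives.

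Oestradiol increased the number of ERα peaks in parental MCF-7 cells. The lists held 6628 and 6545 peaks with E2 and 4225 and 947 with vehicle, ratios of 1.57 and 6.91 in replicates 1 and 2. In both E2 samples 1656 regions were found, 25% of replicate 1 (exact 95% interval 23.9% to 26.0%), against a mean of 18.7 regions after shifting the peaks locally. Of these, 1426 were in neither vehicle sample and counted as gained. In both vehicle samples 140 regions were found, of which 6 were in neither E2 sample and counted as lost. With replicate 1 alone 6412 regions were gained and 4006 lost, and with replicate 2 alone 6333 and 735. With 2 samples against 2 an exact permutation test cannot go below p = 0.33. Lists of the same number of strongest peaks gave 467 gained and 30 lost regions.

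Around known receptor targets, the regions found in both E2 samples numbered 7 inside GREB1 (chromosome 2, 11482888 to 11642788) and 2 for TFF1, of which the region on chromosome 21 from 42366412 to 42366964 overlaps the higher coordinate of the gene's interval (42362282 to 42366535; the gene table used here gives no strand). XBP1 had 3 within 50 kb, PGR, MYC and ESR1 2 each, CCND1 and RARA 1 each, and NUTF2 0. By the authors' fold, the strongest gained region was on chromosome 7 from 152575063 to 152575612, in no protein-coding gene and 69.2 kb from XRCC2 (fold 25.9). The next were inside ZNF385B on chromosome 2 (179646546 to 179647191), 40 kb from GPR139 on chromosome 16 (19987890 to 19988257), inside DOCK1 on chromosome 10 (126918167 to 126918737) and inside CSK on chromosome 15 (74789134 to 74789469). Of the gained regions on main chromosomes, 48.3% lay in a protein-coding gene, and 51.9% did so after local shifts.

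**Figure D4:**
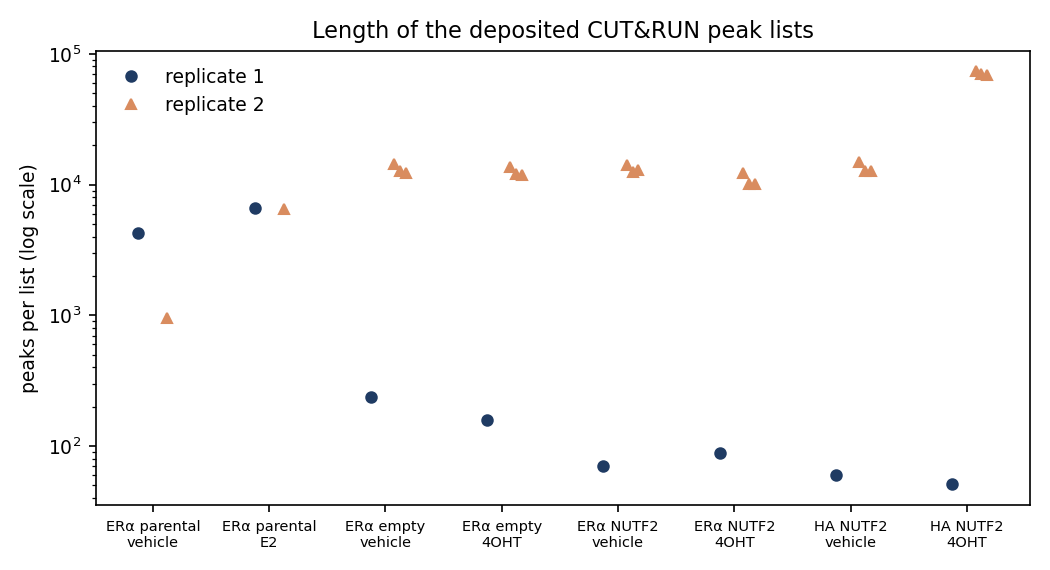
Number of peaks in each of the 28 deposited lists, on a log axis, by antibody, line and treatment. Circles are replicate 1 and triangles replicate 2, which has 3 lists per sample in the stable lines. Lists of the stable lines, whose lowest −log10 q is 2 to 2.21 against 1.3 to 1.32 in parental MCF-7, hold 51 to 236 peaks in replicate 1 and 10108 to 73363 in replicate 2.

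In the stable lines the ERα lists of the 2 replicates differed far more than the treatments did. With 4OHT against vehicle, the number of peaks was 0.665 and 0.952 times as high in the empty-vector line (replicates 1 and 2) and 1.25 and 0.82 times as high in the NUTF2 line. For NUTF2 against empty vector, the ratios were 0.301 and 1.01 with vehicle and 0.567 and 0.867 with 4OHT. Vehicle lists of the empty-vector line held 236 peaks in replicate 1 and a mean of 13111 ± 1160 in replicate 2 (SD over 3 files of 1 sample). The 3 files of such a sample shared few peaks, 1.56% to 2.56% of a list for ERα. Regions in at least 2 files of replicate 2 numbered 756 and 874 in the empty-vector line with vehicle and 4OHT, and 668 and 549 in the NUTF2 line. Of the 668, 23 were shared with the empty-vector line (3.44%, exact 95% interval 2.19% to 5.12%). Chance gave 0.172% after local shifts and 0.41% at random. Over both replicates with vehicle, the share of NUTF2-line regions found in the empty-vector line was 3.52%, and 2.34% on main chromosomes only. It was 47.6% at −log10 q of at least 5 (interval 32.0% to 63.6%) and 21.2% with regions in all files. These stricter sets were not examined on main chromosomes alone. None of the ERα sets of the stable lines had a region within 50 kb of the 9 named loci, except 1 near CCND1 with 4OHT in the empty-vector line. The lowest −log10 q in a list was 2 to 2.21 in the stable lines and 1.3 to 1.32 in parental MCF-7, so the thresholds of these lists differ.

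HA peaks in the NUTF2 line numbered 60 with vehicle and 51 with 4OHT in replicate 1, a ratio of 0.85, and 13424 ± 1250 and 71095 ± 2100 in replicate 2, a ratio of 5.3 (SD over 3 files of 1 sample). In replicate 2, 578 regions with vehicle and 23020 with 4OHT were in at least 2 files. Of the vehicle regions 21 overlapped an ERα region of the same line and treatment (3.63%, exact 95% interval 2.26% to 5.5%). Chance gave 0.197% after local shifts and 0.472% at random. Of the 4OHT regions 24 overlapped one (0.104%, interval 0.0668% to 0.155%), where chance gave 0.0226% after local shifts and 0.0217% at random. The ERα sets held 668 regions with vehicle and 549 with 4OHT. As the HA set with 4OHT was far longer than both, its low share does not show that overlap with ERα fell. In replicate 1 the overlaps were 1 of 60 and 2 of 51. ERα sets of replicate 2 shared 2.97% to 3.46% of regions between treatments or lines. The vehicle share of HA was thus not particular to HA with ERα. With vehicle, both replicates together gave a share of HA regions with ERα of 3.45%, and 2.4% on main chromosomes only. It was 38.6% at −log10 q of at least 5 (interval 24.4% to 54.5%) and 18.6% with regions in all files. With 4OHT in replicate 2, HA regions lay within 50 kb of TFF1 (2), PGR (2) and ESR1 (4) and of none of the other 6 loci, numbers that were not compared with chance and that a set of 23020 regions makes hard to read. The strongest HA region with 4OHT was on chromosome 1 from 125180036 to 125180427, 3720 kb from LINC02798, the nearest gene annotated as protein-coding, and a region at the same place ranked second with vehicle (125180015 to 125180427). With vehicle the first was on chromosome 11 (58826110 to 58826561), 7.5 kb from GLYATL2.

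Genes that differed between the lines did not carry ERα peaks more often than other genes. With each chromosome scaled by itself 2221 of the 2229 calls were lost, so these genes were picked mostly by their chromosome. The tests below therefore cannot tell whether genes changed apart from their chromosome lie near receptor sites. A region found in both E2 samples lay within 10 kb of 6.82% of the genes that rose, 6.56% of those that fell and 6.38% of those not called (Fisher's exact test, two-sided, odds ratios 1.07 and 1.03, adjusted p = 0.638 and 0.82 over 6 tests). For ERα in the empty-vector line the odds ratios were 0.756 and 0.627, and for HA in the NUTF2 line 0.624 and 0.718 (adjusted p = 0.629 for the first 3 and 0.638 for the last). The direction was not stable, in part on few genes. From HA replicate 1 alone the odds ratio of genes that fell was 3.95 (exact 95% interval 0.705 to 15, 3 genes with a peak, adjusted p = 0.251). With HA peaks of −log10 q of at least 5, that of genes that rose was 1.93 (interval 0.0392 to 19.5, 1 gene with a peak, adjusted p = 1). From E2 replicate 1 alone that of genes that fell was 0.885 (adjusted p = 0.407). The genes with such an E2 region that rose most were IL24 (1.67), ZBTB37 (1.30), NOS1AP (0.96) and PLK3 (0.91) on chromosome 1 and HOXC10 (0.94) on chromosome 12. Those that fell most were NCAM2 (-2.00), N6AMT1 (-1.24) and TMPRSS3 (-0.91) on chromosome 21, and NFATC1 (-0.96) and HAUS1 (-0.90) on chromosome 18. With each chromosome scaled by itself none of these 10 was called. IL24 and PLK3 lost their calls without NUTF2 replicate 3 (adjusted p = 0.112 and 0.167), and HOXC10 and TMPRSS3 without it (adjusted p = 0.157 and 0.0727) or NUTF2 replicate 2 (adjusted p = 0.1 and 0.129). N6AMT1 and HOXC10 did so without NUTF2 replicate 1 (adjusted p = 0.0954 and 0.0586), NCAM2 (adjusted p = 0.0513) and N6AMT1 (adjusted p = 0.0855) without NUTF2 replicate 2. Without empty-vector replicate 3, PLK3, HOXC10, N6AMT1 and TMPRSS3 were not called (adjusted p = 0.0818, 0.0899, 0.0527 and 0.0726), without replicate 2 PLK3 and N6AMT1 (adjusted p = 0.053 and 0.0565), and without replicate 1 HOXC10 (adjusted p = 0.0573).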

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

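Scaling each chromosome by itself, its use with the replicate block, thinning, leaving out pseudogenes and matching by chromosome or length were chosen after seeing the data. NUTF2 kept its direction and call under every alternative run (log2 fold change 1.49 to 1.63). The 2229 calls stayed within 1.5 times with RLE (2211), upper-quartile scaling (2248), DESeq2 (2659), no filter (2377), at least 10 counts per library (2215), thinning (1704) and no pseudogenes (2202). They were 1230 with limma-voom, 1053 at an adjusted p under 0.01, 73 with an absolute log2 fold change of at least 1, and 1148 to 2427 when a library was left out. With each chromosome scaled by itself 8 remained, 2221 of the calls being lost; this scaling removes shifts of whole chromosomes. With the replicate block 3161 genes were called, and 46 (24 rose, 22 fell) with block and chromosome scaling. Same-numbered libraries correlated at 0.545, 0.095 and 0.167 in their deviations from the group means, not all above 0.1, so the numbers were not taken to pair the libraries; pairs of different numbers ranged from -0.527 to 0.531 (empty-vector replicate 2 with NUTF2 replicates 1 and 3).

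Of 62 named genes called besides NUTF2, RLE, upper-quartile scaling and the block kept 62, limma-voom 44, and chromosome scaling 5 with 56 lost and 1, TFF1, turned from -0.44 to 0.11 (adjusted p = 0.92). The oestradiol-induced list stayed uncalled under every alternative run. Of 2 lists called, 0 were with an estimated correlation. The estimate was 0.232 for interferon-stimulated and 0.994 for mitochondrially encoded genes, where the calls used the preset 0.01. The 6 tests of changed genes at peaks stayed uncalled in all 40 alternatives that gave an odds ratio above 0 (lowest adjusted p = 0.251; odds ratios 0.561 to 3.95).

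The 1426 gained and 6 lost regions became 467 and 30 with lists of equal length, 981 and 1 at −log10 q of at least 5, 1154 and 16 at 50% reciprocal overlap, and 6333 to 6412 gained and 735 to 4006 lost with a single replicate. The mean log2 ratio of ERα peaks, 4OHT over vehicle, went from -0.33 to 0.07 in the empty-vector line with regions in all files, and from 0.02 to 0.64 in the NUTF2 line at −log10 q of at least 5; NUTF2 over empty vector with 4OHT went from -0.51 to -1.01, and HA, 4OHT over vehicle, from 1.09 to 3.18, with regions in all files. In the empty-vector line, 4OHT regions shared with vehicle were 2.72%, but 19.8% at −log10 q of at least 5, 1.68% on main chromosomes, 1.81% with regions in any file, 9.68% in all files, and 1.27% to 2.97% by replicate. In the NUTF2 line 3.29% became 35.3%, 1.71% (any file) and 15.7% (all files). NUTF2 regions shared with the empty-vector line went with vehicle from 3.52% to 47.6%, 1.71% and 21.2%, and with 4OHT from 3.29% to 39.2%, 1.62% and 13.9%, in the same order. HA regions with 4OHT shared with vehicle went from 0.173% to 0.669%, 1.26% and 0.664%, to 1.16% with equal lists, and ranged from 0.169% to 1.96% by replicate. HA regions shared with ERα went with vehicle from 3.45% to 38.6%, 1.29% and 18.6%, to 5.19% at 50% reciprocal overlap, and 1.67% to 3.63% by replicate; with 4OHT from 0.113% to 0.602%, 0.996% and 0.586%, to 1.03% with equal lists, and 0.104% to 3.92% by replicate. The cause of these moves was not tested. The motif alternatives (no mismatch, whole peak) were not run. Depth limits genes of low count: thinned libraries left 10715 genes to test.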

Other observations

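The following tests were chosen only after the result was seen: those of read-pair loss, random mates, the mitochondrial genome, depth, chromosome parts and the HA lists, and the test of oestradiol-induced genes at E2 regions. Genes that oestradiol induces carried ERα regions of parental MCF-7 far more often than other genes. Of 54 measured members, 30 (55.6%) had a region found in both E2 samples within 10 kb, against 6.24% of 13385 other genes (odds ratio 18.8, 95% interval 10.6 to 33.7, Fisher's exact p = 3.56e-22). The list was drawn up as genes that respond to oestradiol, so it is not independent of receptor binding. The same genes had no common direction in the NUTF2 line.

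Median shifts between the RNA libraries of the lines differed by chromosome, from -0.643 on chromosome 18 to 0.579 on chromosome 1, with chromosome 16 near none (0.016). Each chromosome was split at the middle of its genes of at least 10 CPM, not at the centromere. In 0 of 23 did the medians of the upper and lower part differ by more than 0.2. This argues against gains or losses that set these parts of a chromosome apart, but arms as such were not compared. The share of CUT&RUN peaks did not follow the RNA shift (slope -0.145, bootstrap 95% interval -0.301 to 0.057). This cannot decide on a whole-chromosome copy number difference, since it was not shown that peak share follows copy number in these lists. The SD of the shifts was 0.306 after thinning and 0.307 before. Random thinning keeps each chromosome's expected share of counts, so it shows only that drawing fewer counts does not make the shifts. The shift rose with a chromosome's share of empty-vector counts (Spearman's rho 0.98 across 23 chromosomes, which are not independent replicates), so a loss of read pairs that depends on how many reads a chromosome holds is a candidate explanation for the nuclear chromosomes, though not in the simple form of mates paired at random, which needs a slope of 1 on log2 share and not 0.32 (interval 0.273 to 0.41). Share alone does not account for the mitochondrial genome, which held 4.31% of empty-vector counts and lay -1.02 from the line through the 23 chromosomes (-0.59 without NUTF2 replicate 1; residual SD 0.0881). An effect of NUTF2 stays open and untested, because library depth and line cannot be separated here.

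Most of the 10 genes with the highest fold changes were members of near-identical families, a group read from the folds and not fixed before. Of 140 pseudogenes (median 2.6 CPM) 6.43% rose and 4.29% fell, against 0.875% and 0.656% of 457 lncRNA genes (2.18 CPM) and 11.2% and 6.01% of protein-coding genes (32.5 CPM), differences that were not tested. Pseudogenes named after a tested parent, 62 in number, had a median of 0.13 relative to their chromosomes, above the upper limit of the middle 95% of matched draws (0.087) but not the highest of 1000 (0.158), so a different division of reads between a gene and its copies cannot be told apart from no such effect. Lower depth by itself stays open too: 6 of 6 copies called relative to their chromosomes kept a log2 fold change of at least 1 after thinning, but they were picked for their rise and 3 of them fell under the filter at that depth. An effect of NUTF2 on these genes is untested.

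The HA lists of replicate 2 were longer with 4OHT. The rise was absent in replicate 1 (ratio 0.85). In replicate 2 the vehicle set held 578 regions and the 4OHT set 23020. Of the 4OHT regions, 37 (0.161%, interval 0.113% to 0.221%) lay at the 1656 E2 sites. ERα regions of the same line and treatment were overlapped by 24. The listed sites, 1656 with E2 and 549 ERα regions with 4OHT, are too few for a large share of 23020 regions at any overlap. The low shares were thus largely set by the lengths of the lists. They cannot decide whether regions at receptor sites make up the added length. Receptor sites outside these lists were not tested. Chance overlaps with E2 sites averaged 1.26 regions after local shifts and 3.2 at random for the vehicle set, and 11.2 and 12.7 for the 4OHT set. The ratio of the vehicle set thus depends on the placement. The 4OHT set overlapped E2 sites 3.31 times as often as after local shifts, less than the vehicle set (12.7 times). This leaves open whether tagged protein at receptor sites increased with 4OHT. HA in the empty-vector line and IgG were not analysed here.

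Of the 10 splits of the 6 RNA libraries into groups of 3, 1, the real one, called 2229 genes, and the highest other called 0; 10 splits are too few for a share under 0.05. With each chromosome scaled by itself the real split called 8, while the split of empty-vector replicate 1 with NUTF2 replicates 1 and 2 against the rest called 510, which points to a structure of the libraries other than their group.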
